A study of Mus musculus with 6 samples.

How the data were processed

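Total RNA of gastrocnemius muscle from young and aged male mice was extracted, labelled with biotin and hybridised to 6 Affymetrix arrays, 1 sample per array, per the labels' protocols. The deposited values are 1 linear intensity per probe set, made with MAS5 per the submitters' processing notes. The software version and its settings are not given in the sources used here. In the deposited table the mean of each array after trimming 2% of probe sets at each end was 1500, so each array had been scaled to that mean, and no further normalization between arrays was seen. Such scaling assumes that the trimmed mean is alike in all samples, and MAS5 signals of dim probe sets vary more on the log scale. The run settings deposited with each array were used only for the fluidics protocol and station. No array duplicated another.

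Intensities were taken to log2 as deposited, and 64 control probe sets were left out. Probe sets whose mean log2 signal over the 6 arrays lay below the median, 9.08 (a signal of 540), were left out as dim, since the table holds no detection calls. This left 22519 probe sets. Aged and young muscle were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend of the spread with brightness, a two-sided test and Benjamini-Hochberg adjustment over all tested probe sets, at a threshold of 0.05. Fixed lists were tested with camera at a preset correlation of 0.01, over 1 probe set per gene, the one with the highest mean signal, with Benjamini-Hochberg adjustment over the 34 lists that had at least 5 measured genes. The same test with an estimated correlation and fry were run beside it. The ratio of 3 prime to 5 prime control signal was compared with an exact permutation test. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

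Genes were named from the platform's gene table. It lists 34958 probe sets with 1 symbol and 932 with several, which stayed unnamed, and 9160 probe sets other than controls are not in it. Of those with 1 symbol 34754 matched the reference by gene ID, and 0 symbols were updated. The tested probe sets named 11763 genes. Of the 140 genes chosen by the rule for named genes 63 had several tested probe sets, which pointed in one direction for 38 and in both for 25, and 0 genes had calls in both directions.

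The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The 35 lists held 847 genes, of which 766 had a named probe set and 676 were measured. They covered slow-twitch and fast-twitch fibres, sarcomere, calcium handling, denervation, atrophy, proteasome, oxidative phosphorylation in a pair of lists, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, lipid synthesis, matrix, ribosomal proteins, heat shock, p53 and senescence, antigen presentation, complement, antioxidants, clock, immediate early genes, growth factors and polyamine metabolism. The others held markers of fat cells, blood, macrophages, lymphocytes, endothelium, smooth muscle, fibroblasts, Schwann cells, tendon, satellite cells and dividing cells. The text names the 12 genes with the greatest rise and the 12 with the greatest fall among genes that passed and whose groups did not overlap. It also names up to 4 members of a list that shifted or held a called gene, up to 2 of another list, and 11 genes always named if measured. Genes with only provisional names are counted but not named among the 24, the next gene taking their place. Genes outside the rule are said to have been chosen after their values were seen.

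Alternatives were quantile normalization, median centring, no filter or a stricter one, a pseudocount of 219 (the 25th percentile of all signals), array weights, each array left out in turn, the fluidics station as a covariate, eBayes without the trend or robust, an unmoderated linear model, a 1.5-fold minimum, probe sets prone to cross-hybridisation left out, and for lists all probe sets of a gene averaged. A covariate of RNA quality and the arrays of the first station alone were added after seeing the data. The median change over all tested probe sets was 0.0079 as deposited, -0.02 after quantile normalization and -0.06 after median centring.

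The steps were tested on simulated data in 10 simulations with 200 changed probe sets each among 22519. Changed probe sets were called in 1.04% of cases at 2-fold, 18.4% at 4-fold and 48.2% at 16-fold, and 3.02% of calls were false. A simulated list of 20 genes shifted by -1 on the log2 scale was called in 10 of 10 simulations with the preset and 5 with the estimated correlation, and 1 and 0 of 330 unchanged lists were called. The simulated genes varied independently of each other. These counts therefore do not show how either setting does on lists of correlated genes. The median standard error of a log2 fold change was 0.559, and it fell with brightness, from 0.938 in the dimmest to 0.279 in the brightest of 5 groups.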

Results

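Gene expression was measured in the gastrocnemius, the large calf muscle, of young and aged male mice. The arrays were 6 Affymetrix mouse genome arrays, 3 of young muscle (replicates 1, 2 and 3) and 3 of aged muscle (replicates 51, 52 and 53). Each array reported 45101 probe sets, and the median signal of an array lay between 635 and 832. Ages in months are not given in the sources used here. The labels do not say that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Changes are aged minus young on the log2 scale, given with limma's standard error and n = 3 per group, and each adjusted p of a gene is limma's with Benjamini-Hochberg adjustment.

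The comparison of aged with young muscle asked which transcripts differ with age in this muscle. Genes of the extracellular matrix and of slow-twitch fibres fell in aged muscle. Lists of fat cell and lipid synthesis genes were higher by their medians, with 4 of 11 and 4 of 27 genes past the test, and neither list passed with an estimated correlation (adjusted p = 0.143 and 0.133). Col1a1, a chain of type I collagen, was 52.3-fold higher in young muscle (log2 fold change -5.71 ± 0.32). The slow light chain Myl2 was 12.9-fold higher in young muscle (-3.69 ± 0.27), and fatty acid synthase, Fasn, was 12.3-fold higher in aged muscle (3.62 ± 0.42). Of 22519 probe sets tested, 237 passed an adjusted p of 0.05, with 70 higher and 167 lower in aged muscle. They belonged to 178 named genes, 50 higher and 128 lower. At an unadjusted p under 0.05 there were 2262. On all 237 the 3 aged arrays lay on one side of the 3 young arrays, as on 16.2% of all tested probe sets, where chance gives 10%. Without the trend of the spread with brightness 21 probe sets passed, 2 higher and 19 lower, and with an unmoderated linear model 0 passed. The count was 131, 124 and 152 without young replicate 1, 2 and 3, and 149 without aged replicate 52. All young arrays and aged replicate 51 were washed on one fluidics station, and aged replicates 52 and 53 on another, under another protocol name. With the ratio of 3 prime to 5 prime control signal as a covariate 138 passed. With the station as a covariate 294 passed, and among the arrays of the first station alone 365 passed. That last fit sets 1 aged array against 3 young ones, so the spread of aged muscle is taken from the young arrays. The covariate's estimate equals the difference within the first station by construction, and there Col1a1 was at -5.19, Myl2 at -3.71 and Fasn at 2.58.

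The genes with the greatest rise were Ighm, the heavy chain of immunoglobulin M (6.28 ± 0.73, adjusted p = 0.000977), Rasd2 (4.47 ± 0.45), Nrip2 (3.76 ± 0.72), Fasn and Mrap, an accessory protein of melanocortin receptors (3.55 ± 0.43). They were followed by the lectin Lgals3 (3.34 ± 0.67), the carboxylesterase Ces1d (3.17 ± 0.39) and the ATP citrate lyase Acly (2.91 ± 0.33). Hsd11b1, which regenerates active glucocorticoid (2.89 ± 0.41), the muscle ubiquitin ligase Fbxo32 (2.86 ± 0.39), the ubiquitin ligase Mib1 (2.72 ± 0.31) and the adipogenic transcription factor Cebpa (2.57 ± 0.44) completed the 12. The young means of Ighm, Rasd2 and Mrap lay below the filter on dim probe sets, and with a pseudocount their changes were 5.05, 3.76 and 3.06. Of 7 tested Ighm probe sets 5 were higher and 1 passed, and the other Nrip2 probe set was at -0.79. Of 5 tested Acly probe sets 4 were higher and 2 passed. The probe sets that stood for Ighm, Rasd2 and Acly are of a kind prone to cross-hybridisation, and no other Rasd2 probe set was tested. All probe sets of Ces1d (3), Mib1 (3) and Fbxo32 (2) were higher, and 1 of each passed. Nrip2 did not pass without young replicate 1, 2 or 3 or aged replicate 51 or 53 (adjusted p 0.0544 to 0.117). Lgals3 did not pass without young replicate 1 or 2 or aged replicate 52 or 53 (adjusted p 0.0635 to 0.118), and Cebpa did not without aged replicate 52 (adjusted p = 0.0658). With the station as a covariate Fbxo32 was at 2.21 (adjusted p = 0.0726), and with the ratio as a covariate Lgals3 was at 1.94 (adjusted p = 0.41).

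The genes with the greatest fall were Ecrg4 (-7.57 ± 0.65, adjusted p = 8.60e-05), Col1a1, the slow troponin T gene Tnnt1 (-4.77 ± 0.51), the slow myosin heavy chain Myh7 (-4.68 ± 0.74) and Col1a2 (-4.62 ± 0.22). Cthrc1 (-4.32 ± 0.89), the slow light chain Myl3 (-4.24 ± 0.33), the type III collagen gene Col3a1 (-3.89 ± 0.21) and the imprinted noncoding RNA Rian (-3.72 ± 0.77) came next. Myl2, the muscle LIM protein Csrp3 (-3.55 ± 0.61) and the tendon protein Tnmd (-3.47 ± 0.60) completed the 12. The aged means of Ecrg4, Tnnt1, Cthrc1 and Rian lay below the filter, and with a pseudocount their changes were -6.22, -4.00, -2.95 and -3.04. The other Ecrg4 probe set was at -0.58 and did not pass (adjusted p = 0.639), and of 4 tested Rian probe sets all were lower and 1 passed, the weakest at -0.72. The probe sets that stood for Ecrg4 and Myl3 are of a kind prone to cross-hybridisation. All 3 tested Myl3 probe sets were lower, and 2 passed. Without young replicate 1, 2 or 3 neither Cthrc1 (adjusted p 0.302 to 0.405) nor Tnmd (adjusted p 0.054 to 0.0656) passed. Rian did not pass without young replicate 1, 2 or 3 or aged replicate 52 (adjusted p 0.0746 to 0.175), and with the RNA quality covariate it was at -1.34 (adjusted p = 0.452) and with the station as a covariate at -2.22 (adjusted p = 0.351). Csrp3 did not pass without young replicate 2 or 3 (adjusted p 0.0505 to 0.0841), and Myh7 did not without young replicate 2 (adjusted p = 0.0533). With the station as a covariate Csrp3 was at -5.34 and Tnmd at -5.29.

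**Figure D1:**
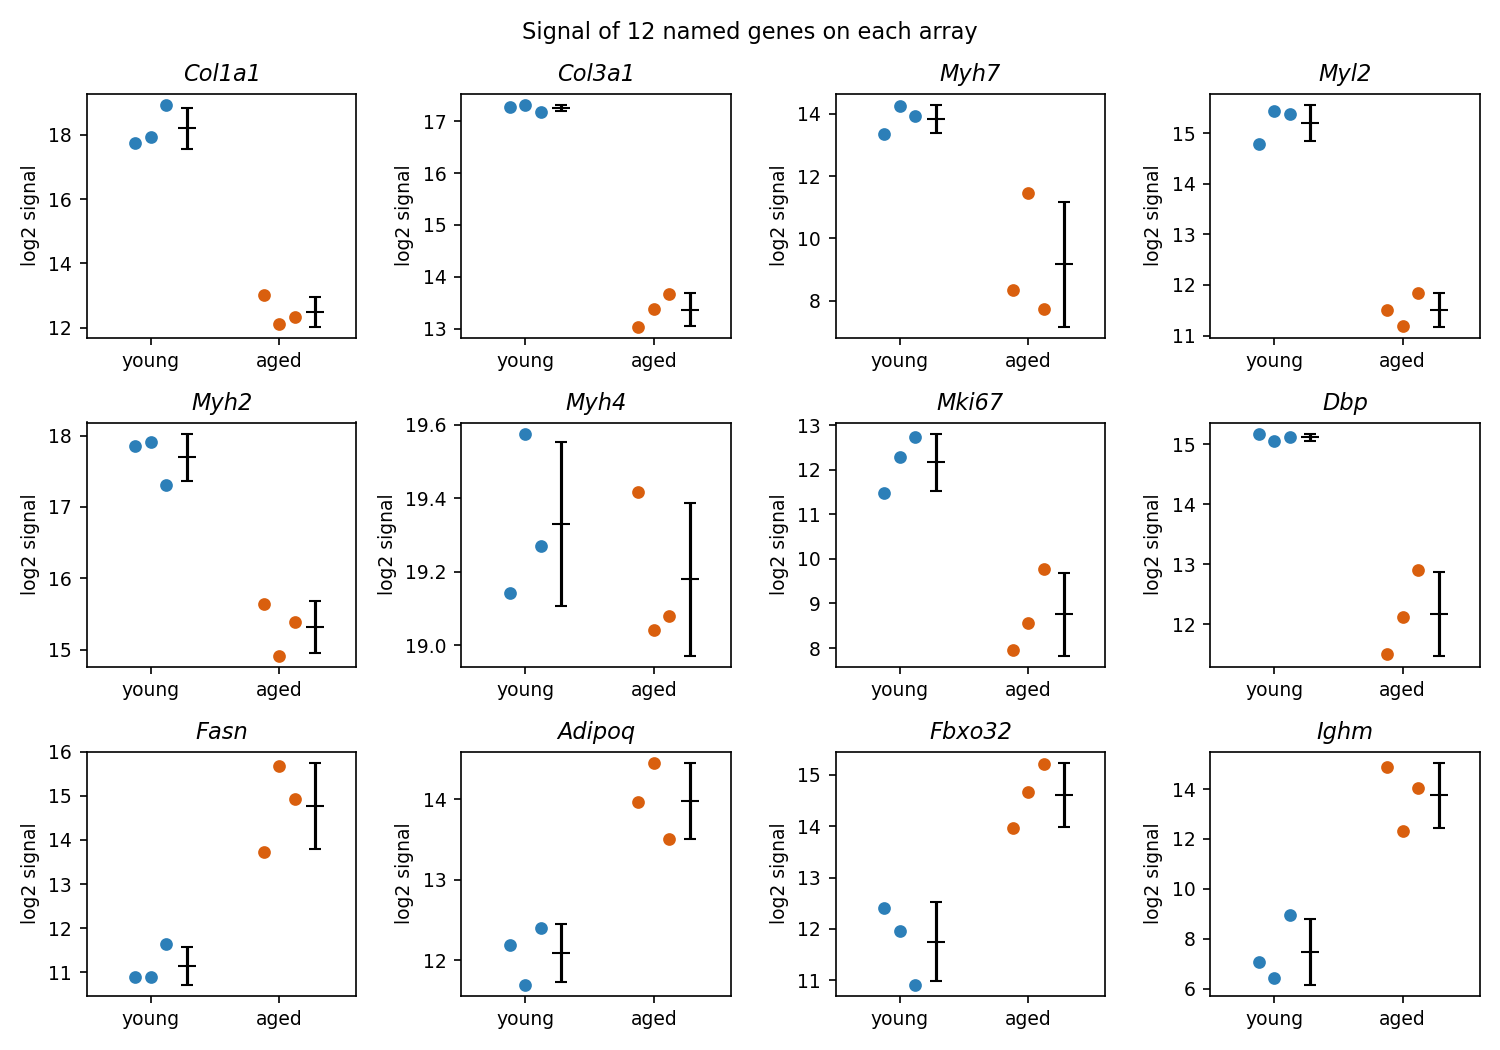
Log2 signal of 12 named genes on each of the 3 young (blue) and 3 aged (orange) arrays, with a panel and a vertical axis for each gene; points are arrays, and the black mark and bar are the mean and SD of the group. The groups overlap for Myh4 (-0.15) and lie apart for the other genes, such as Col3a1 (-3.89) and Fasn (3.62).

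Matrix genes fell together. Of 30 measured collagens and other matrix genes 16 fell, 0 rose and 14 did not pass, and all 30 had a negative change. Adjusted over the list alone 23 fell. The median was -1.59 (camera adjusted p = 1.39e-36, adjusted p = 0.015 with an estimated correlation). Col1a2 was 24.6-fold and Col3a1 14.8-fold higher in young muscle. The collagen-binding protein Sparc fell by 3.08, with its other probe sets at -2.82 and 0.01. Of 13 measured tendon markers 3 fell and 10 did not pass, and adjusted over the list alone 6 fell (median -1.09, camera adjusted p = 1.85e-07, adjusted p = 0.0482 with an estimated correlation). Beside Tnmd these were the tendon proteoglycans Kera (-2.40 ± 0.32) and Fmod (-1.46 ± 0.23, with 1 of 6 probe sets called and the weakest at -0.21). Of 15 measured fibroblast markers 5 fell and 10 did not pass, and adjusted over the list alone 8 fell and 1 rose (median -1.13, camera adjusted p = 1.81e-06, adjusted p = 0.0483 with an estimated correlation). They were Pcolce, which enhances procollagen processing (-2.13 ± 0.25), the secreted glycoprotein Fstl1 (-2.77 ± 0.35), Dpt (-1.13 ± 0.22), Mfap5 (-2.94 ± 0.59) and Cd34, which was chosen after its values were seen (-1.65 ± 0.34). Within the first station the medians were -1.50 for matrix genes, -1.22 for tendon markers and -0.56 for fibroblast markers. The ratio of 3 prime to 5 prime signal, called RNA quality here, was higher on the aged arrays by 0.58, and with it as a covariate the medians were -1.65, -1.35 and -1.26. The aged mean of Mfap5 lay below the filter on dim probe sets, and its change was -2.36 with a pseudocount. With the covariate Mfap5 was at -1.78 (adjusted p = 0.381), and the fibroblast median was -0.68 without aged replicate 52. With 1 array left out 2 to 4 of the 15 fibroblast markers passed, with Pcolce and Fstl1 among them each time. Mfap5 did not pass without young replicate 1, 2 or 3 (adjusted p 0.167 to 0.202), Dpt without young replicate 1, 2 or 3 or aged replicate 51 or 52 (adjusted p 0.07 to 0.203), and Fmod without young replicate 1 or 2 (adjusted p 0.0518 to 0.0563).

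Slow-twitch fibre genes fell. Of 14 measured 9 fell, 0 rose and 5 did not pass, and adjusted over the list alone 12 fell (median -2.63, camera adjusted p = 1.18e-22, adjusted p = 0.0409 with an estimated correlation). Myl3 was 19-fold higher in young muscle. The slow and cardiac troponin C gene Tnnc1 (-3.00 ± 0.30), Myoz2, which binds calcineurin at the Z disc (-2.63 ± 0.26), and Atp2a2, the calcium pump of slow fibres (-2.05 ± 0.22), fell as well. All 3 tested Atp2a2 probe sets were lower and 1 passed, the weakest at -0.73. With the RNA quality covariate Myh7 was at -2.96 and did not pass (adjusted p = 0.228). Of 18 measured fast-twitch genes 2 fell and 16 did not pass, and adjusted over the list alone 7 fell (median -0.56, camera adjusted p = 5.59e-06, adjusted p = 0.0679 with an estimated correlation). These were Myh2, the heavy chain of type 2A fibres (-2.38 ± 0.25), and the light chain Myl1 (-1.04 ± 0.22). The heavy chain of type 2B fibres, Myh4, did not pass (-0.15 ± 0.26, adjusted p = 0.872). With 1 array left out 1 to 4 of the 18 fast-twitch genes passed. Of 26 measured genes of the dystrophin complex, costamere and sarcomere 0 passed, and adjusted over the list alone 2 fell (median -0.46, camera adjusted p = 0.000271, adjusted p = 0.192 with an estimated correlation). Of 25 measured calcium handling genes Atp2a2 fell and 24 did not pass, and adjusted over the list alone 4 fell (median -0.12, camera adjusted p = 0.0873). The calcium handling list passed in 5 alternatives: with the station as a covariate (-0.38, adjusted p = 0.0128), within the first station (adjusted p = 0.00835), with the RNA quality covariate (-0.28, adjusted p = 0.0069), without young replicate 3 (-0.19, adjusted p = 0.0452) and without aged replicate 53 (-0.20, adjusted p = 0.0132). Its median was 0.057 without aged replicate 51, and 1 to 5 of its genes passed with 1 array left out. Within the first station the medians were -2.70 for slow-twitch genes, -0.63 for fast-twitch genes and -0.68 for the sarcomere list, and with the RNA quality covariate they were -2.68, -0.54 and -0.87. Without aged replicate 51 the sarcomere median was -0.27. Myl1 did not pass without young replicate 1, 2 or 3 or aged replicate 51 or 52 (adjusted p 0.065 to 0.274).

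**Figure D2:**
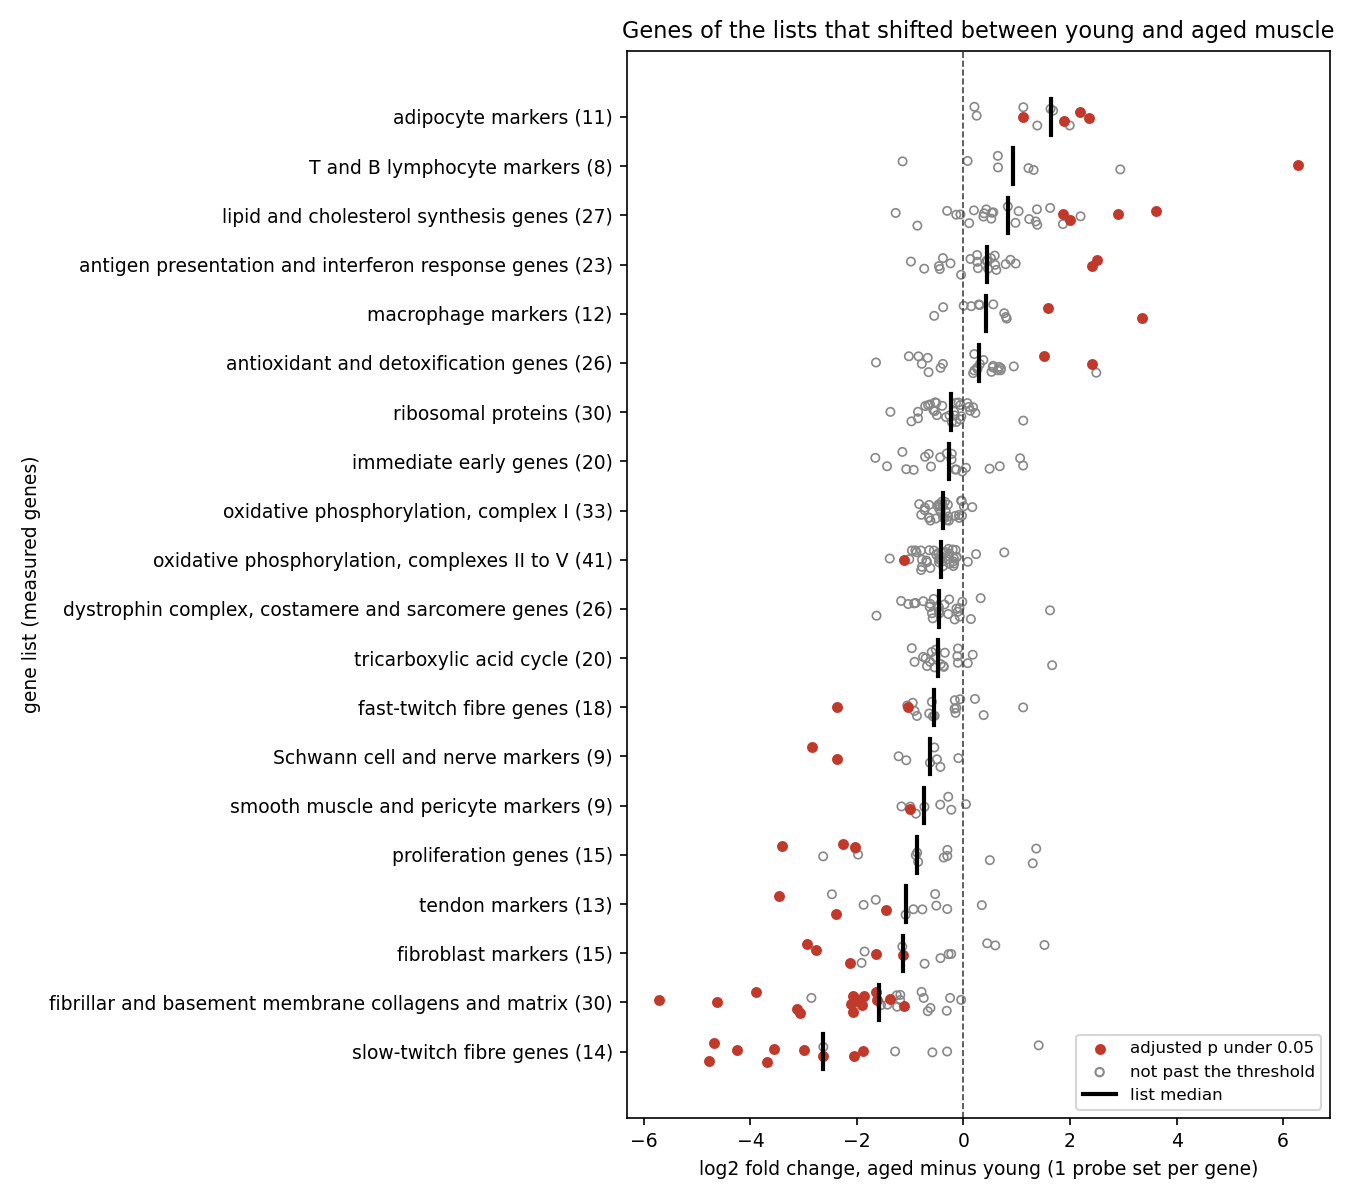
Log2 fold change, aged minus young, of each measured gene (horizontal axis) in the 20 lists that shifted (vertical axis, with the number of measured genes), where filled circles passed an adjusted p of 0.05, open circles did not, and the black bar is the median. The medians run from -2.63 for slow-twitch genes to 1.63 for adipocyte markers.

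Lists of mitochondrial respiratory chain genes had smaller negative medians, and nearly all of their genes did not pass. For complexes II to V 38 of 41 measured genes had a negative change, 1 fell and 40 did not pass, and adjusted over the list alone 12 fell (median -0.43, camera adjusted p = 1.51e-09, adjusted p = 0.0614 with an estimated correlation). The called gene was Atp5o, a subunit of the ATP synthase (-1.12 ± 0.22, other probe set -0.62). With 1 array left out 0 to 4 of the 41 passed. For complex I 31 of 33 were negative and 0 passed, also adjusted over the list alone (median -0.38, camera adjusted p = 1.59e-06, adjusted p = 0.311 with an estimated correlation). For the tricarboxylic acid cycle 17 of 20 were negative and 0 passed, and adjusted over the list alone 1 was higher and 1 lower (median -0.47, camera adjusted p = 0.000561, adjusted p = 0.382 with an estimated correlation). Of 30 measured ribosomal protein genes 0 passed, and adjusted over the list alone 2 fell (median -0.24, camera adjusted p = 0.000365, adjusted p = 0.199 with an estimated correlation). The median change of the brightest probe sets was -0.11. Among 10000 random lists matched on brightness, the ribosomal median lay at percentile 10.4, that of complexes II to V at 0.07 and that of complex I at 0.65. The random lists were drawn gene by gene, so these percentiles leave out the correlation among genes of a list. Of 26 fatty acid uptake and oxidation genes only Fabp3, a muscle fatty acid carrier, fell (-1.33 ± 0.23, other probe set 0.21), 2 fell adjusted over the list alone, and the list did not shift (median -0.01, camera adjusted p = 0.51). Of 21 glycolysis and glycogen genes only Pgam2, a muscle phosphoglycerate mutase, fell (-1.02 ± 0.21), and adjusted over the list alone 2 rose and 2 fell (median 0.15, camera adjusted p = 0.498). Within the first station the medians were -0.39 for complexes II to V, -0.48 for complex I, -0.66 for the tricarboxylic acid cycle and -0.27 for ribosomal proteins. In the same order they were -0.27, -0.21, -0.35 and -0.14 after quantile normalization, and -0.49, -0.62, -0.74 and -0.43 with the RNA quality covariate. Without aged replicate 51 the tricarboxylic acid cycle was at -0.24 (adjusted p = 0.04). Without aged replicate 53 there were 1 higher and 3 lower ribosomal protein genes past the test. Neither Atp5o (adjusted p 0.0647 to 0.184) nor Pgam2 (adjusted p 0.0953 to 0.276) passed without young replicate 1, 2 or 3 or aged replicate 51 or 52, and Fabp3 did not without young replicate 1, 2 or 3 or aged replicate 52 (adjusted p 0.0505 to 0.105).

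Lists of fat cell and lipid synthesis genes were higher in aged muscle. Of 11 measured adipocyte markers 4 rose, 0 fell and 7 did not pass, and adjusted over the list alone 7 rose (median 1.63, camera adjusted p = 1.73e-09, adjusted p = 0.143 with an estimated correlation). They were the adipokines Retn (2.35 ± 0.36) and Adipoq (1.89 ± 0.30), the lipogenic regulator Thrsp (2.18 ± 0.35) and the fatty acid carrier Fabp4 (1.11 ± 0.23, with 1 of 4 probe sets called and the lowest at -0.63). Of 27 measured lipid and cholesterol synthesis genes 4 rose, 0 fell and 23 did not pass, and adjusted over the list alone 10 rose and 2 fell (median 0.83, camera adjusted p = 1.96e-08, adjusted p = 0.133 with an estimated correlation). Beside Fasn and Acly, which was 7.5-fold higher in aged muscle, these were the fatty acid elongase Elovl6 (2.01 ± 0.37, lowest of 3 probe sets -0.22) and Insig1, which restrains sterol synthesis (1.87 ± 0.35). The medians of both lists were 1.21 and 0.58 within the first station, and with the RNA quality covariate 2.22 and 1.00. Fabp4 did not pass without young replicate 1, 2 or 3 or aged replicate 52 (adjusted p 0.165 to 0.253), and Adipoq (adjusted p = 0.0501) and Thrsp (adjusted p = 0.0536) did not without young replicate 2. Elovl6 did not pass without young replicate 1, 2 or 3 or aged replicate 52 or 53 (adjusted p 0.0514 to 0.136), and Insig1 did not without young replicate 1 or 2 or aged replicate 52 or 53 (adjusted p 0.0567 to 0.134). With the station as a covariate 0 adipocyte markers passed: Retn was at 1.94 (adjusted p = 0.105), Adipoq at 1.88 (adjusted p = 0.0695), Thrsp at 1.45 (adjusted p = 0.129) and Fabp4 at 0.74 (adjusted p = 0.288). The list as a whole still passed there (adjusted p = 0.000648). Averaging the probe sets of each gene lowered the lipid synthesis median to 0.50 (adjusted p = 6.38e-08), and leaving out young replicate 2 lowered the adipocyte median to 1.05.

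The medians of immune lists were positive, with few genes past the test. Of 8 measured lymphocyte markers Ighm rose and 7 did not pass, and adjusted over the list alone 3 rose and 1 fell (median 0.93, camera adjusted p = 0.0104, adjusted p = 0.138 with an estimated correlation). Without probe sets prone to cross-hybridisation, a kind to which the called Ighm probe set belongs, the lymphocyte median was 0.36 and 0 genes were called. With the RNA quality covariate it was 2.00 with 0 called (adjusted p = 0.00635). The list did not pass with the probe sets of a gene averaged (median 0.65, adjusted p = 0.147) or with fry (adjusted p = 0.067). Jchain, which joins immunoglobulin units, was at 2.94 ± 0.70 (adjusted p = 0.0911, and 2.35 with a pseudocount, as its young mean lay below the filter). Of 12 measured macrophage markers Lgals3 and the lysosomal protease Ctss (1.58 ± 0.32) rose and 10 did not pass, and adjusted over the list alone 2 rose (median 0.43, camera adjusted p = 0.00411, adjusted p = 0.382 with an estimated correlation). Of 23 measured antigen presentation and interferon genes 2 rose and 21 did not pass, and adjusted over the list alone 2 rose (median 0.43, camera adjusted p = 0.0104, adjusted p = 0.138 with an estimated correlation). They were the class II gene H2-Aa (2.41 ± 0.30) and the interferon-induced Ifi27l2a (2.51 ± 0.36). B2m, the light chain of class I molecules, did not pass (-0.39 ± 0.28, adjusted p = 0.671, other probe set 0.31). Within the first station the medians were 1.41 for lymphocyte markers, 0.83 for macrophage markers and 0.15 for antigen presentation genes. With only 1 aged array there, the antigen presentation list had an adjusted p of 0.102 (0.0871 with the station as a covariate), which leaves open whether it shifted apart from the station. Its median was 0.19 with the RNA quality covariate and 0.19 without probe sets prone to cross-hybridisation. The lymphocyte list did not pass without aged replicate 51 (adjusted p = 0.0728, range over all alternatives 0.0037 to 0.147). The macrophage list did not pass without aged replicate 51 or 53 (adjusted p = 0.0584 and 0.0594, range 5.13e-06 to 0.478) or with the RNA quality covariate (median 0.26, adjusted p = 0.478). Its median was 0.29, 0.86 and 0.28 without aged replicate 51, 52 and 53, and 0.28 with the probe sets of a gene averaged. With 1 array left out Ctss passed only without aged replicate 52 (adjusted p 0.0525 to 0.168 in the others). Ctss was at 0.81 with the RNA quality covariate (adjusted p = 0.376).

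Lists of nerve, smooth muscle and dividing cell markers were lower in aged muscle. Of 9 measured Schwann cell and nerve markers the myelin genes Mbp (-2.85 ± 0.27, highest of 7 probe sets 0.18) and Pmp22 (-2.37 ± 0.30) fell and 7 did not pass, and adjusted over the list alone 3 fell (median -0.63, camera adjusted p = 1.54e-05, adjusted p = 0.0603 with an estimated correlation). Of 9 measured smooth muscle and pericyte markers the actin gene Acta2 fell (it was 2.01-fold higher in young muscle) and 8 did not pass, and adjusted over the list alone 3 fell (median -0.73, camera adjusted p = 0.000561, adjusted p = 0.0805 with an estimated correlation). Of 15 measured proliferation genes 3 fell and 12 did not pass, and adjusted over the list alone 5 fell and 1 rose (median -0.87, camera adjusted p = 0.000507, adjusted p = 0.192 with an estimated correlation). They were the marker of cycling cells Mki67 (-3.41 ± 0.57), the DNA replication factor Mcm5 (-2.04 ± 0.39) and the ribonucleotide reductase subunit Rrm2 (-2.26 ± 0.48). The aged mean of Mki67 lay below the filter, and its change was -2.85 with a pseudocount. The called probe sets of Mcm5 and Rrm2 are of a kind prone to cross-hybridisation, and their other probe sets were at -0.31 (adjusted p = 0.882) and -0.42 (adjusted p = 0.846). The only tested probe set of Acta2 is of that kind too. Without probe sets of that kind the proliferation median was -0.42 with 1 of 13 genes called. The calls in the list changed with 1 array left out: without young replicate 2 none passed, and without young replicate 3 there were 1 higher and 0 lower. Without young replicate 2 Mki67, Mcm5 and Rrm2 were at -3.35, -2.08 and -2.22, so their changes hardly moved where the calls were lost. The medians of these lists were -0.52, -0.92 and -0.93 within the first station. The proliferation median was -1.46 with a stricter filter on dim probe sets and -1.36 with the RNA quality covariate, and the Schwann cell median was -1.07 with the stricter filter and -1.05 without aged replicate 51. Mki67 did not pass without young replicate 2 or 3 (adjusted p 0.08 to 0.109), and Rrm2 did not without young replicate 1, 2 or 3 or aged replicate 51 or 52 (adjusted p 0.108 to 0.183). Without young replicate 1, 2 or 3 or aged replicate 52 neither Acta2 (adjusted p 0.108 to 0.177) nor Mcm5 (adjusted p 0.0811 to 0.191) passed.

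The antioxidant list had a small positive median and the immediate early list a small negative one, with 2 of 26 and 0 of 20 genes past the test. Of 26 measured antioxidant and detoxification genes the extracellular glutathione peroxidase Gpx3 (2.41 ± 0.39) and Mgst1 (1.51 ± 0.31) rose and 24 did not pass, and adjusted over the list alone 2 rose (median 0.28, camera adjusted p = 0.0305, adjusted p = 0.23 with an estimated correlation). Of 20 measured immediate early genes 0 passed and adjusted over the list alone 1 fell (median -0.27, camera adjusted p = 0.0269, adjusted p = 0.149 with an estimated correlation). Within the first station the antioxidant median was -0.05 (adjusted p = 0.668) and the immediate early median -0.24 (adjusted p = 0.259). With the station as a covariate the adjusted p values were 0.553 and 0.345, and 1 antioxidant gene was called lower and 0 higher. The first station holds 1 aged array, so these values do not show that the lists are unchanged. The antioxidant list did not pass without young replicate 1 or aged replicate 52 or 53 (adjusted p = 0.0506, 0.142 and 0.104, range over all alternatives 0.00508 to 0.668). The immediate early list did not without young replicate 2 or aged replicate 53 (adjusted p = 0.106 and 0.14, range 0.0107 to 0.437). With 1 array left out the antioxidant median ran from 0.19 without young replicate 1 to 0.44 without young replicate 3. The immediate early median ran from -0.45 without young replicate 1 to -0.19 without young replicate 2, and was -0.44 with a stricter filter on dim probe sets. With the RNA quality covariate neither the antioxidant (adjusted p = 0.145) nor the immediate early list (adjusted p = 0.437) passed. Gpx3 did not pass without aged replicate 52 (adjusted p = 0.0713), and Mgst1 did not without young replicate 1, 2 or 3 or aged replicate 52 or 53 (adjusted p 0.0609 to 0.2). With the station as a covariate Mgst1 was at 0.85 (adjusted p = 0.307).

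Single genes changed in lists that did not pass in camera over all arrays. Of 17 measured clock genes the output regulator Dbp (-2.94 ± 0.31, adjusted p = 0.000497) and Per3 (-2.56 ± 0.35, highest of 4 probe sets 0.10) fell, and adjusted over the list alone 4 fell. The other Dbp probe set was at -1.04 and did not pass. The clock list's median was 0.23, while its mean was -0.24 and its test pointed down (camera adjusted p = 0.158). With a stricter filter on dim probe sets its median was -0.29 and it passed (adjusted p = 0.0381), and its median was -0.17 with the station as a covariate. Of 26 growth factor and insulin signalling genes the growth factor Igf1 (-1.76 ± 0.21, highest of 4 probe sets 0.24) and the imprinted receptor adaptor Grb10 (-1.39 ± 0.21) fell, and adjusted over the list alone 4 fell (median -0.22, camera adjusted p = 0.118). The growth factor list passed with fry (adjusted p = 0.0133) and with no filter on dim probe sets (median -0.15, adjusted p = 0.0484). Of 24 atrophy and FoxO genes Fbxo32 rose, and adjusted over the list alone 1 rose and 1 fell (median 0.21, camera adjusted p = 0.286). Of 21 p53 target and senescence genes the cell cycle inhibitor Cdkn1c fell (-2.34 ± 0.33), and adjusted over the list alone 1 rose and 3 fell (median -0.05, camera adjusted p = 0.49). The cell cycle inhibitor Cdkn1a (0.69 ± 0.34, adjusted p = 0.532) and the acetylcholine receptor subunit Chrna1 (-0.35 ± 0.51, adjusted p = 0.845) did not pass. Cdkn2a, Chrng and Hba-a1 lay below the filter, and Mstn had 0 named probe sets. Grb10 did not pass without young replicate 1 or 3 (adjusted p 0.0505 to 0.0517).

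The other lists had 0 genes past the threshold over all probe sets. The medians were -0.20 for 31 proteasome subunits (camera adjusted p = 0.286), -0.23 for 13 satellite cell markers (0.35) and -0.20 for 18 denervation and neuromuscular junction genes (0.35). They were 0.06 for 10 complement and acute phase genes (0.49), -0.05 for 26 heat shock genes (0.498), 0.03 for 26 polyamine and amino acid genes (0.498) and -0.17 for 14 endothelial markers (0.498). The proteasome list passed in 5 alternatives: with the RNA quality covariate (-0.47, adjusted p = 0.00244), with the station as a covariate (-0.30, adjusted p = 0.0119), within the first station (adjusted p = 0.00708), without aged replicate 53 (-0.35, adjusted p = 0.0127) and with the probe sets of a gene averaged (-0.21, adjusted p = 0.0313). Adjusted over the list alone 2 satellite cell markers and 1 denervation gene fell, and 0 genes passed in the other lists named here. Only 3 erythroid markers were measured, too few to test (median 0.05, mean -0.22).

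The ratio of 3 prime to 5 prime control signal was higher on the aged arrays. The log2 ratio, averaged over Gapdh and beta-actin, was 1.75 ± 0.03 (SD, n = 3) in young and 2.33 ± 0.47 in aged muscle. All aged arrays lay above all young arrays (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). Aged replicate 53 was at 2.86, and without it the difference was 0.31. Taken alone, Gapdh had a young SD of 0.15 and beta-actin 0.11. Their young values ran in opposite order, so the average varied less than either. The nearest beta-actin values were 1.76 on young replicate 1 and 1.85 on aged replicate 52. The spiked transcripts, which do not come from the muscle, also differed, by 0.57 on average (exact permutation p = 0.1), so the quality of the RNA is not separated from labelling or hybridisation. Arrays of young muscle correlated with each other at r = 0.776 to 0.808 over all tested probe sets, arrays of aged muscle at 0.718 to 0.776, and arrays of different groups at 0.690 to 0.810. Over the brightest probe sets the ranges were 0.939 to 0.949, 0.887 to 0.921 and 0.823 to 0.885. The first principal component held 28.4% of the variance, with the young arrays at -63.5, -55.1 and -40.9 and the aged arrays at 116, 50.6 and -7.20.

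**Figure D3:**
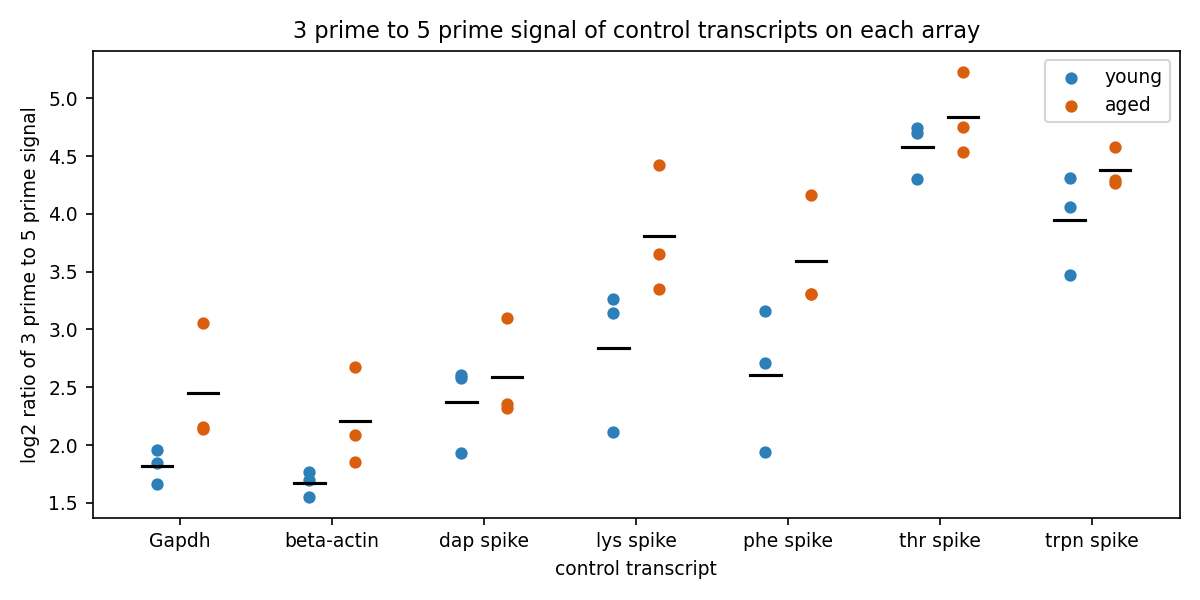
Log2 ratio of 3 prime to 5 prime signal (vertical axis) of Gapdh, beta-actin and 5 spiked bacterial transcripts (horizontal axis) on each young (blue) and aged (orange) array, with the black bar at the mean. The groups lie apart for Gapdh (difference 0.63), beta-actin (0.53), lys (0.97) and phe (0.99).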

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

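The test of fat tissue, the RNA quality covariate and the reading of the whole fibroblast list were chosen only after the result was seen. Of the 5 spiked bacterial transcripts, which are added to the sample and are not part of the comparison of genes, lys and phe differed in the log2 ratio of 3 prime to 5 prime signal. The lys ratio was 2.84 ± 0.63 (SD, n = 3) on young and 3.81 ± 0.56 on aged arrays, a difference of 0.97 with all aged arrays above all young ones (exact permutation p = 0.1, the smallest possible). The phe ratio was 2.60 ± 0.62 and 3.59 ± 0.50, a difference of 0.99 (exact permutation p = 0.1). The ratios of dap, thr and trpn differed by 0.22, 0.26 and 0.43, with overlapping groups.

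Of the 10 splits of the 6 arrays into 3 and 3, the real one called 237 probe sets, and the highest of the others called 0 in limma, with 538 to 1368 at an unadjusted p under 0.05. The real split was 1 of the 10 with as many calls, and 3 against 3 makes 10 splits, too few for a share under 0.05.

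Matrix genes were lower in aged muscle (median -1.59). With the RNA quality covariate the median was -1.65, and 16 of the 16 called genes stayed below 0 by more than 2 standard errors. The ratio used, the average of Gapdh and beta-actin, was higher on all aged arrays than on all young ones. It varied little among the young (SD 0.03, beside 0.15 for Gapdh and 0.11 for beta-actin alone). The fit rests mostly on differences among the 3 aged arrays, and cannot rule out a loss of 5 prime sequence as the whole source. Stray signal on single probe sets is argued against by the 15 of 19 genes with several probe sets that had all of them lower (78.9%). The probe set that stood for each gene was itself lower, so only the other probe sets bore on this, and by sign alone. Fewer connective tissue cells in the aged samples could not be ruled out: 7 abundant fibroblast transcripts had a median of -0.43, above a bound of -0.79 set before the test (permutation p = 0.0152), but that set left out 4 called fibroblast markers, and the whole list of 15 had a median of -1.13, below the bound. The median of that list was -0.68 without aged replicate 52 and -0.56 with the station as a covariate, both above the bound. That explanation therefore remains open, as does a difference of age, which was not tested on its own.

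Slow-twitch fibre genes were lower in aged muscle (median -2.63). With the RNA quality covariate the median was -2.68, and 9 of the 9 called genes stayed below 0 by more than 2 standard errors. For the reason given for matrix genes, this fit cannot rule out a loss of 5 prime sequence as the whole source. More slow muscle, such as soleus, taken with the young samples may account for the pattern: soleus also holds type 2A fibres, and Myh2 was at -2.38 ± 0.25 (limma adjusted p = 0.000497), as this explanation needs. A difference of age in the muscle itself could lower Myh2 too, so Myh2 does not decide between these explanations. That difference stays open, as untested.

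The medians of the adipocyte and lipid synthesis lists were higher in aged muscle, with 4 of 11 and 4 of 27 genes past the test. Neither list passed with an estimated correlation (adjusted p = 0.143 and 0.133), and 0 adipocyte markers passed with the station as a covariate. Fat tissue taken with the aged samples may account for this: 7 measured adipocyte markers outside lipid synthesis had a median of 1.63, beside 2.46 for the 4 called lipid synthesis genes (permutation p = 0.0997 for the difference). Those 4 were picked because they passed in these data, and the whole lipid synthesis list had a median of 0.83. Among the 7 adipocyte markers Plin4 and Lep, chosen after their values were seen (0.25 and 0.20), were far below Retn (2.35). Fat cells within the aged muscle and a difference of age in lipid synthesis stay open, as untested.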

How the results depend on the processing

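The RNA quality covariate and the fit to the first station alone were chosen after the result was seen. The 237 changed probe sets became 21 without the eBayes trend, 0 with an unmoderated linear model, 138 with the RNA quality covariate and 365 within the first station, which has fewer arrays, and 124 to 342 with 1 array left out. The cause was not tested. Quantile normalization gave 241, with 223 of the 237 among them. All 237 kept their sign there and with the RNA quality covariate. They also did so with the station covariate, within the first station and with each array left out. In those last fits no sign could turn, since on all 237 the aged arrays lay on one side of the young ones. The share of lower calls was 70.5%, 88.1% with the station covariate (294 calls), 85.5% within the first station and 59.2% without young replicate 3. Without the eBayes trend it was 90.5%, with 2 calls higher and 19 lower. The number of lists that shifted was 20, and it was 4 with an estimated correlation, all lower, 10 with fry, among them the growth factor list, which is not of the 20, and 18 to 21 with 1 array left out, where lists outside the 20 are counted too. Those 4 were the matrix, slow-twitch, tendon and fibroblast lists. Among the genes that both the rule and the text name, and the 20 lists, signs turned for Chrna1 (-0.72 to 0.13 with 1 array left out, the highest without aged replicate 53, and 0.72 with the RNA quality covariate), B2m (0.19 with that covariate), Myh4 (0.089 with the station covariate and equally within the first station) and the antioxidant list (-0.053 in both). The 3 genes had not passed in the first place. Genes outside the rule were not put through all alternatives, and of these Lep turned (from 0.20 to -0.25 with the RNA quality covariate). Medians of lists that had not shifted turned as well, such as the clock (0.23 to -0.29 with a stricter filter, where it passed), denervation (0.074 without aged replicate 53) and complement lists (-0.41 with the RNA quality covariate). Of 61 called named genes 60 passed after quantile normalization, 30 with the RNA quality covariate and 11 without the trend. Without probe sets prone to cross-hybridisation 49 of the 61 had a value, and 47 of these passed. The probe sets that stood for Ighm, Rasd2, Acly, Ecrg4, Myl3, Acta2, Mbp, Fmod, Mcm5, Rrm2, H2-Aa and Dbp are of that kind. The difference of the RNA quality ratio was 0.31 to 0.74 with 1 array left out. With 3 prime over middle signal it was 0.32 (exact permutation p = 0.4), and the groups overlapped. Signal limits the calls: the brightest of 5 groups held 191 and the dimmest 1. No paired analysis was possible because the groups share no replicate numbers.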

Other observations

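The test of imprinted genes followed the sight of 3 such genes among those that fell, and its prediction was written before it was run. Meg3 (-3.17 ± 0.22), Rian (-3.72 ± 0.77) and Plagl1 (-2.69 ± 0.40), which are expressed from one parental copy, fell in aged muscle. With the RNA quality covariate Rian was at -1.34 ± 0.66 (adjusted p = 0.452), and it did not pass without young replicate 1, 2 or 3 or aged replicate 52 (adjusted p 0.0746 to 0.175). Meg3 and Plagl1, and the other genes of this paragraph outside the rule, were chosen after their values were seen. Of 26 other imprinted genes listed 19 were measured, 13 lay below 0, 3 fell and 0 rose. Those that fell were Ndn (-1.55 ± 0.20), Grb10 (-1.39 ± 0.21) and Cdkn1c (-2.34 ± 0.33). Grb10 did not pass without young replicate 1 or 3 (adjusted p 0.0505 to 0.0517). Grb10, Cdkn1c, Igf2 (which did not pass) and some others of the 19 also stand in fixed lists. The test of the 19 is therefore not independent of the results of those lists. A hypothesis is that imprinted genes as a class may be lower in aged muscle. The median of the 19 was -0.37, and camera gave p = 0.00196 with the preset and p = 0.0691 with an estimated correlation, so it rests on the preset correlation. Usp29 was at 2.47 ± 0.91 and did not pass.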
